A study of Mus musculus with 16 samples.

How the data were processed

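RNA was sequenced from 16 libraries of RAW264.7 cells, 4 each of Parental, ORP5/8 KD, ATP11A/C KD and CDC50A KD. Per the labels' protocols, cells were plated in 6-well plates and collected on the next day in cold buffer, and RNA was purified on RNeasy columns. Libraries were made from 500 ng of RNA with the TruSeq Stranded mRNA kit and sequenced as paired-end reads of 100 bp on an Illumina NovaSeq instrument. The library names of the KD groups begin with "sh", which the labels do not expand, and Parental names no construct. No library with a non-targeting construct was analysed here.

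Per the submitters' processing notes, reads were trimmed with Trim Galore 0.5.0, aligned with STAR 2.7.5a to mm10, checked with Picard and quantified with RSEM. The deposited values are RSEM expected counts per gene, and 4.64% of them carry decimals. The expected counts deposited by the authors were rounded to whole counts before testing. The table holds 55573 gene records, among them 92 ERCC spike-in records whose counts sum to 0. Coordinates came from GENCODE M21 on GRCm38 (mm10), matched by gene identifier without its version for 55394 records and with it for 55094, and 17 tested genes have no coordinates. For 12 tested genes that share a symbol, the record with the higher total count was used for gene lists.

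Samples were grouped by their labels. Genes were kept by filterByExpr with a minimum count of 10, which left 13107 genes holding 100.0% of all counts. Libraries were scaled by TMM, and all 16 were fitted together with the quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with a term for each group. The biological coefficient of variation was 6.86%. The 3 KD groups were compared with Parental and with each other, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05, and counts of genes changed at least 2-fold were also taken. Standard errors were derived from the estimate and its F statistic. Levels are counts-per-million after TMM scaling. The total count per library ran from 24020891 to 41543050, and a gene with no count in any library of a group was given a limit of 3 counts, which covers counting error only.

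Gene names followed a rule fixed before the data were examined. It takes the target genes, the 10 highest and 10 lowest log2 fold changes per KD group against Parental (5 and 5 between KD groups, and 5 and 5 shared by all KD groups) and up to 4 called members of each gene list with the smallest adjusted p. The ranked genes had to be called and protein coding, with no overlap between the 4 and 4 libraries, a mean of at least 10 CPM in the higher group and at least 10 counts summed over the lower group. Genes with predicted-gene names were passed over. Other list members, and Stc1, Cd36 and Ctsh among them, were chosen after their values were seen. Some genes taken by the rule are left out of the text, and the results of 2 of them, withheld for evaluation, are not reported here.

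The 24 gene lists, with 609 genes of which 607 have a symbol in the file, were fixed at the same time. They cover P4-ATPase flippases and CDC50 subunits, lipid scramblases, phosphatidylserine synthesis and lipid transfer at contact sites, phosphatidylserine receptors and efferocytosis, opsonic and pattern-recognition receptors, LC3-associated phagocytosis with the NADPH oxidase, canonical autophagy, lysosome, cholesterol synthesis, LXR targets, interferon-stimulated genes, inflammatory genes, the unfolded protein response, cell cycle, antigen presentation, osteoclast genes, macrophage identity, glycolysis and hypoxia, p53 targets, and markers of fibroblasts, lymphocytes, neutrophils and mast cells, dendritic cells and epithelium. The 21 lists with at least 2 tested genes were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01 and, as an alternative, with the correlation estimated for each list. Adjusted p covers all list tests of the comparisons with Parental together, and those between KD groups likewise. Counts of called members are also given with p-values adjusted over the list alone.

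Overlaps between KD groups share the Parental libraries. They are therefore given beside the value for independent lists, beside 20 simulations of unchanged groups with shared controls, and beside fits in which Parental 1 and 2 served one KD group and 3 and 4 the other. Every split of the 8 libraries of a comparison into 4 and 4 was tested in the same way as the labelled groups. The mitochondrial share of counts and the level of Osbpl5, the latter on the log2 scale, were compared by an exact permutation test of the difference in means.

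The alternatives tried were DESeq2 size factors, upper-quartile scaling, no low-count filter, a filter of 1 CPM in 4 libraries, the replicate number as a block, a fit of the compared groups alone, the Wald test of DESeq2 1.42.0, leaving out each library in turn and, chosen after seeing the data, leaving out the genes of chromosome 12. The procedure was tested on simulated data with 200 changed genes among 12837: it called 82.1% of changes of 1.5-fold, 97.0% of 2-fold and 100.0% of 4-fold, with 4.62% of the calls false, and called 0 genes in a simulated comparison with no change. The real comparisons called from 3428 to 7451 genes, far more than were changed there, so this false share may not hold for them. Osbpl5 and other genes below the filter were left out of the edgeR tests, and reads, transcripts and splice forms were not analysed here.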

Results

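Gene expression was measured by RNA sequencing in RAW264.7 cells, a mouse macrophage-like line established from a tumour induced by Abelson murine leukaemia virus. The 16 libraries fell into 4 groups of 4: the parental line (Parental) and 3 knockdowns (KD), which the labels name ORP5/8 KD, ATP11A/C KD and CDC50A KD. ORP5 and ORP8, encoded by Osbpl5 and Osbpl8, are lipid transfer proteins that carry phosphatidylserine from the endoplasmic reticulum to the plasma membrane at membrane contact sites. ATP11A is a flippase (a P4-type ATPase), which moves phosphatidylserine to the cytoplasmic leaflet of the plasma membrane. CDC50A, encoded by Tmem30a, is the subunit with which most such flippases leave the endoplasmic reticulum. The series title concerns clustering of phosphatidylserine and LC3-associated phagocytosis, in which LC3 is attached to the membrane of the phagosome. The labels describe cells collected on the day after plating and name no phagocytic cargo.

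The deposited counts summed to 32779753, 37353063, 27885958 and 33225372 in Parental 1 to 4, and to 36355337, 41543050, 39058963 and 35478120 in ORP5/8 KD 1 to 4. They summed to 40927250, 32538835, 40754730 and 31771196 in ATP11A/C KD 1 to 4, and to 40668919, 24020891, 34430805 and 40445718 in CDC50A KD 1 to 4. Levels are given in counts-per-million (CPM) as mean ± SD over the 4 libraries of a group. Log2 fold changes are given as estimate ± standard error from edgeR. The labels number the replicates in each group but do not say that they were separate cultures, so p-values measure the spread between these libraries, which may be technical. Mitochondrial genes held 1.19% ± 0.0744 (SD, n = 4) of the counts in Parental, 1.68% ± 0.112 in ORP5/8 KD, 1.56% ± 0.194 in ATP11A/C KD and 1.63% ± 0.151 in CDC50A KD. Each KD group lay above Parental (exact permutation test, 2-sided p = 0.0286 each, the smallest p that 4 against 4 libraries allow). Of 55573 gene records, 13107 passed the low-count filter and were tested.

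Osbpl8 (ENSMUSG00000020189.14; mm10 chromosome 10, 111164752 to 111297249, plus strand) was lower than in Parental in all 3 KD groups, not in ORP5/8 KD alone. Its level was 337 ± 5.84 CPM in Parental (n = 4), 99.1 ± 8.17 in ORP5/8 KD, 127 ± 8.99 in ATP11A/C KD and 116 ± 4.41 in CDC50A KD, which is 29.4%, 37.6% and 34.5% of the Parental mean. The log2 fold changes were -1.77 ± 0.0562 (adjusted p = 1.72e-16), -1.41 ± 0.0555 (2.33e-14) and -1.54 ± 0.0559 (6.99e-15). In the direct comparisons, Osbpl8 was lower in ORP5/8 KD than in ATP11A/C KD by a log2 fold change of -0.36 (adjusted p = 2.64e-05) and than in CDC50A KD by -0.23 (0.00148). Osbpl5 (ENSMUSG00000037606.18; chromosome 7, 143688762 to 143756985, minus strand) had 2 to 13 counts per library and was below the filter of the edgeR test. It stood at 0.176 ± 0.107 CPM in ORP5/8 KD (28 counts summed) against 0.140 ± 0.0722 in Parental (18 counts), or 126% of the Parental mean, so these counts show no loss of Osbpl5 where it was targeted, while a partial fall could be missed at such counts. Its means were 0.198 ± 0.15 in ATP11A/C KD and 0.143 ± 0.0917 in CDC50A KD (exact permutation test against Parental, 2-sided p = 0.771, 0.6 and 0.971 in ORP5/8, ATP11A/C and CDC50A KD).

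Atp11a (ENSMUSG00000031441.15; chromosome 8, 12757014 to 12868728, plus strand) was lowest in ATP11A/C KD, at 21.4 ± 0.843 CPM against 61.4 ± 1.91 in Parental (log2 fold change -1.52 ± 0.0437, adjusted p = 1.09e-16). It was also lower in CDC50A KD, at 43.1 ± 1.36 CPM (-0.51, adjusted p = 2.89e-09), and in ORP5/8 KD, at 53.3 ± 0.604 (-0.21, adjusted p = 3.44e-04).

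Tmem30a (ENSMUSG00000032328.12; chromosome 9, 79768943 to 79793507, minus strand) was 127 ± 5.8 CPM in CDC50A KD against 162 ± 4.83 in Parental, 78.6% of the Parental mean (log2 fold change -0.35 ± 0.0612, adjusted p = 7.95e-05). It was 130 ± 10.4 in ORP5/8 KD (-0.31, adjusted p = 2.83e-04) and 142 ± 13.1 in ATP11A/C KD (-0.19, adjusted p = 0.0196). The libraries labelled CDC50A KD were not set apart from the other KD groups by Tmem30a: the log2 fold change of ORP5/8 KD against CDC50A KD was 0.04 (adjusted p = 0.6), and that of CDC50A KD against ATP11A/C KD was -0.16 (0.0566). The latter passed the threshold without ATP11A/C KD 1 (-0.22, adjusted p = 0.0061) or CDC50A KD 2 (-0.20, 0.0421), under upper-quartile scaling (-0.18, 0.0369), under a filter of 1 CPM in 4 libraries (-0.17, 0.0409) and by DESeq2 (-0.17, 0.0375). The Tmem30a call in ATP11A/C KD ended without Parental 1 (adjusted p = 0.0706), ATP11A/C KD 1 (0.0717) or ATP11A/C KD 3 (0.0572).

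**Figure D1:**
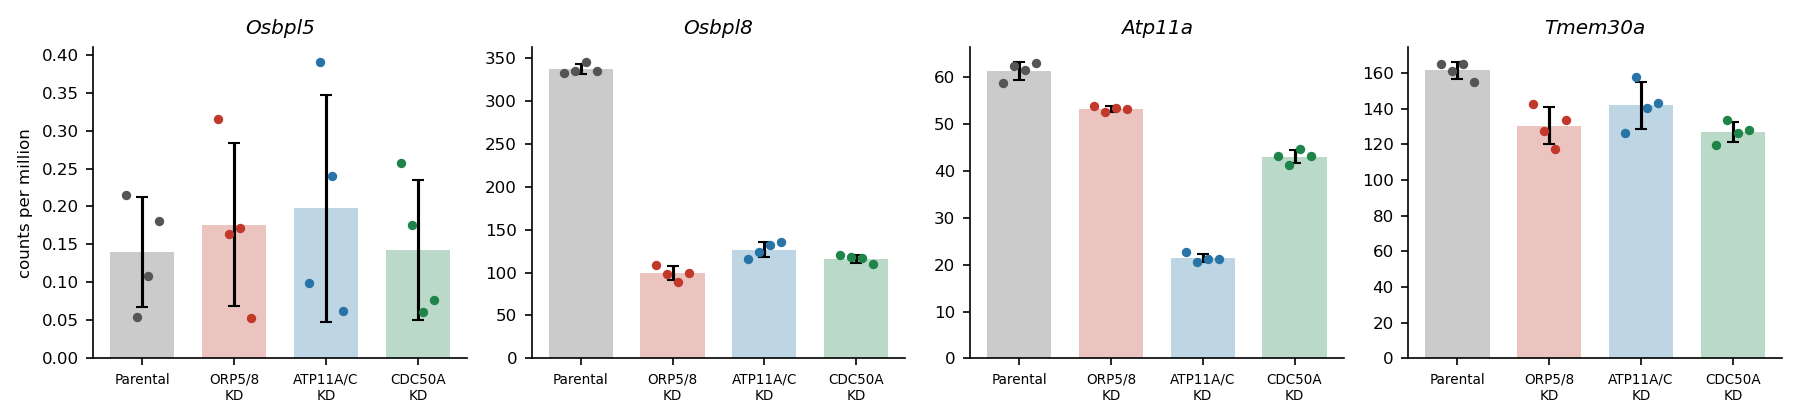
Level in counts-per-million (vertical axes, from 0) of Osbpl5, Osbpl8, Atp11a and Tmem30a in each of the 16 libraries (points), with the mean (bar) and SD (error bar) of the 4 libraries of each group. Osbpl8 is at 99.1 to 127 CPM in the 3 KD groups against 337 in Parental, Atp11a is lowest in ATP11A/C KD at 21.4, and Tmem30a is at 127 to 142 in the KD groups against 162.

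ORP5/8 KD was compared with Parental to see which genes differ when the lipid transfer proteins are targeted. Interferon-stimulated genes, inflammatory genes and opsonic and pattern receptor genes were lower, while Chst1 and the MHC class II genes H2-Ab1 and H2-Eb1 were among the higher genes. Isg15, a ubiquitin-like protein induced by interferon (chromosome 4, 156199424 to 156200818), fell from 118 ± 5.32 CPM to 5.97 ± 1.27 (n = 4 each; log2 fold change -4.30 ± 0.104). Chst1, a sulfotransferase of keratan sulfate (chromosome 2, 92599707 to 92615250), rose from 1.69 ± 0.0583 to 36.0 ± 2.98 CPM, or 21.2-fold. In total 2878 genes were higher and 3181 lower at an adjusted p under 0.05, of which 305 and 552 changed at least 2-fold (185 higher under a filter of 1 CPM in 4 libraries). Higher genes made up 47.5% of the calls, and 63.3% under upper-quartile scaling. They also outnumbered the lower ones without Parental 2 (2823 and 2808) or ORP5/8 KD 1 (3000 and 2945).

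All 44 tested interferon-stimulated genes of 46 listed were lower in ORP5/8 KD, also when adjusted over the list alone. Their median log2 fold change was -2.58 (camera adjusted p = 2.94e-48, and 0.0156 with an estimated correlation). Irf7, a transcription factor of the type I interferon response, fell from 632 ± 18.3 to 44.0 ± 3.82 CPM (-3.85 ± 0.0694). The RNA sensors Ifih1 and Ddx58 had log2 fold changes of -2.48 and -2.23, Oasl2 of -4.75, and Zbp1, a sensor of Z-form nucleic acid, of -5.04. Those of Ifit1 and Ifit3, which bind viral RNA, were -3.95 and -4.40, and that of Ifi211 was -4.48. Apol9b and Apol9a, a near-identical pair of apolipoprotein L genes whose reads could be split between them, had log2 fold changes of -6.15 ± 0.149 and -4.86 ± 0.0949. Ifi27 went the other way, from 28.9 ± 2.48 to 109 ± 1.97 CPM (1.91 ± 0.0592).

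Of 29 tested inflammatory cytokine and NF-kB target genes, 25 were lower and 1 was higher in ORP5/8 KD, with the same counts when adjusted over the list alone (median -1.19, camera adjusted p = 3.2e-17). Tnf fell from 65.7 ± 3.7 CPM by a log2 fold change of -1.72 ± 0.076, and Acod1, the enzyme that makes itaconate, from 48.3 ± 1.03 to 3.80 ± 0.514 (-3.67). The chemokines Ccl5 and Ccl4 had log2 fold changes of -4.21 ± 0.153 and -2.56 ± 0.0951, Cd40 of -3.93 ± 0.198, Nos2 of -2.60 ± 0.133, and Ptgs2, an enzyme of prostaglandin synthesis, of -1.64 ± 0.111. Marcksl1 fell from 118 ± 5.14 to 23.7 ± 1.04 CPM.

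Antigen presentation genes moved in 2 directions in ORP5/8 KD: of 21 tested, 7 were higher and 13 lower, with the same counts when adjusted over the list alone. The class II genes H2-Ab1 and H2-Eb1 rose from 0.0675 ± 0.0242 to 2.73 ± 0.265 CPM (5.24 ± 0.289) and from 0.0596 ± 0.0816 to 1.79 ± 0.0761 (4.96 ± 0.485), and Ciita, the transactivator of class II genes, from 0.0818 ± 0.0576 to 2.81 ± 0.431 (adjusted p = 1.44e-10). Among the lower members, H2-T23 fell by 1.93, the peptide transporter Tap1 by 1.47, the proteasome subunit Psmb8 by 1.22 and B2m, the light chain of class I molecules, by 1.08 on the log2 scale. The list's median was -0.80 and its mean 0.51, while the test called it lower (camera adjusted p = 0.00609). The call was lost, with adjusted p = 0.184 with an estimated correlation.

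Phagocytic receptors that bind opsonins or microbial patterns were mostly lower in ORP5/8 KD: 17 of 26 tested were lower and 2 higher (3 higher and 17 lower when adjusted over the list alone; median -0.55, camera adjusted p = 8.41e-07). The scavenger receptor Msr1 fell from 322 ± 8.08 to 131 ± 8.23 CPM (-1.29 ± 0.0616), and the Fc receptor Fcgr1 from 160 ± 8.77 to 79.4 ± 3.01 (-1.01). The C-type lectin receptors Clec4e and Clec4d had log2 fold changes of -1.25 and -1.02. Among 24 tested phosphatidylserine receptor and efferocytosis genes, 14 were lower and 3 higher, with the same counts when adjusted over the list alone (median -0.18, camera adjusted p = 0.0198; adjusted p = 0.0809 with an estimated correlation). This call ended without Parental 1, 2 or 4 or ORP5/8 KD 4 (adjusted p = 0.0546, 0.0515, 0.0611 and 0.0503). Cd36, a scavenger receptor, fell from 85.0 ± 1.52 to 36.5 ± 2.75 CPM (-1.22 ± 0.0699), and Anxa1 from 228 ± 6.78 to 112 ± 3.27. Gas6, which bridges phosphatidylserine to TAM receptors, rose from 41.4 ± 2.48 to 70.5 ± 5.83 (0.77 ± 0.067), and the integrin gene Itgb5 from 39.0 ± 2.16 to 64.6 ± 4.95.

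In the list of P4-ATPases and CDC50 subunits, 9 of 10 tested members were lower and none higher in ORP5/8 KD, also when adjusted over the list alone (median -0.24, camera adjusted p = 0.00126). Among them Atp8b4 fell from 161 ± 0.637 to 99.3 ± 3.59 CPM. Of 13 lipid scramblase genes, 6 were lower and none higher, also when adjusted over the list alone (camera adjusted p = 0.0363; adjusted p = 0.0654 with an estimated correlation). The scramblase call ended without Parental 1 or 4 or ORP5/8 KD 1 or 4 (adjusted p = 0.0583, 0.0551, 0.0537 and 0.0551). Ano10 and Tmem41b had log2 fold changes of -0.54 and -0.38. Of 24 tested genes of phosphatidylserine synthesis and lipid transfer, 4 were higher and 7 lower (6 and 7 when adjusted over the list alone). This list was not called (camera adjusted p = 0.494). Osbpl10 fell from 3.06 ± 0.302 to 0.807 ± 0.155 CPM, and Ptdss2, a phosphatidylserine synthase, rose from 41.6 ± 3.36 to 53.6 ± 1.22.

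The list for LC3-associated phagocytosis and the NADPH oxidase was not called in ORP5/8 KD (median -0.06, camera adjusted p = 0.496). Of its 26 tested members 5 were higher and 8 lower, with the same counts when adjusted over the list alone. Cybb, the catalytic subunit of the oxidase, fell from 1485 ± 15.5 to 1062 ± 56.3 CPM (-0.48 ± 0.0442), and Map1lc3b, which encodes LC3B, rose from 65.4 ± 1.39 to 83.1 ± 3.49 (0.35 ± 0.0386). Rubcn, a regulator of this form of phagocytosis, stood at 37.8 ± 0.75 against 39.2 ± 1.47 CPM (-0.05 ± 0.0578, adjusted p = 0.5). Canonical autophagy genes were not called either (11 of 29 higher and 7 lower, 12 and 9 when adjusted over the list alone, camera adjusted p = 0.496). In that list Atg2b rose by a log2 fold change of 0.50 and the cargo receptor Sqstm1 fell by 0.49.

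Genes of cholesterol synthesis were lower in ORP5/8 KD: 17 of 24 were lower and none higher (18 lower when adjusted over the list alone; median -0.37, camera adjusted p = 3.15e-08). Hsd17b7 and Fdft1 fell by 0.58 and 0.48 on the log2 scale. LXR target genes were not called (6 of 17 higher and 5 lower, the same counts when adjusted over the list alone, camera adjusted p = 0.881). Lipoprotein lipase, Lpl, fell from 1252 ± 25.4 to 485 ± 22.4 CPM. The unfolded protein response list was lower, with 25 of 30 genes lower and 2 higher, also when adjusted over the list alone (median -0.32, camera adjusted p = 1.35e-08). The chaperone Hspa5 (BiP) fell from 2358 ± 47 to 1777 ± 91.3 CPM (-0.41 ± 0.0392), Edem1 by 0.73, and the stress-induced Trib3 and Ddit3 by 1.57 and 1.29 on the log2 scale.

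Lysosomal genes were lower by count in ORP5/8 KD, with 28 of 47 lower and 11 higher (30 and 11 when adjusted over the list alone; camera adjusted p = 0.001; adjusted p = 0.202 with an estimated correlation). The cathepsins Ctsd, Ctsb and Ctss had log2 fold changes of -0.89, -0.68 and -0.69. Macrophage identity genes were lower, 16 of 22 with 2 higher, also when adjusted over the list alone (median -0.33, camera adjusted p = 1.06e-05). Siglec1, the sialoadhesin receptor, fell from 98.3 ± 1.57 to 6.25 ± 0.709 CPM (-3.97 ± 0.0769), and the transcription factor Maf from 2.37 ± 0.826 to 0.0881 ± 0.0758. Lyz2, which shares near-identical sequence with Lyz1, fell from 7207 ± 301 to 4168 ± 170. Osteoclast genes had 9 of 18 lower and 3 higher (11 and 3 when adjusted over the list alone; camera adjusted p = 0.0388; adjusted p = 0.0654 with an estimated correlation), a call that ended under a filter of 1 CPM in 4 libraries (0.0674). The fusion protein Dcstamp and Car2, carbonic anhydrase, had log2 fold changes of -2.24 and 0.99.

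Cell cycle genes (12 of 35 higher and 6 lower, 12 and 7 when adjusted over the list alone; camera adjusted p = 0.406), glycolysis and hypoxia genes (3 of 25 higher and 7 lower, the same when adjusted over the list alone; 0.221) and p53 targets (3 of 18 higher and 8 lower, the same when adjusted over the list alone; 0.113) were not called in ORP5/8 KD. With no low-count filter the p53 targets were called lower (adjusted p = 0.0385). Within these lists the p53 target Sesn1 rose from 52.8 ± 1.49 to 133 ± 3.74 CPM (1.34 ± 0.0375), while Cdkn1a, the cell cycle inhibitor p21, fell from 265 ± 9.13 to 115 ± 5.76. Beyond the lists, the genes higher in ORP5/8 KD by the fixed rule were led by Cnnm1 (4.48 ± 0.15), Chst1 (4.41), Scel (4.24) and Ranbp3l (3.76). They were followed by the chemokine receptor Cxcr4 (3.10), Cxxc5 (2.59), the proapoptotic Bmf (2.25), the heparan sulfate enzyme Ndst1 (2.19) and Lrrc32 (1.83). Stc1 had no counts in Parental and 1.76 ± 0.222 CPM in ORP5/8 KD, at least 76.6-fold higher than the limit of 3 counts summed over the Parental libraries, a limit that covers counting error only.

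ATP11A/C KD was compared with Parental to see which genes differ when the plasma membrane flippases are targeted. Hpgd, which encodes an enzyme that degrades prostaglandins, and Chst1 rose from low levels, and Lyz1, Ccl5 and the interferon-stimulated genes were lower. Hpgd (chromosome 8, 56294585 to 56321043) rose from 1.00 ± 0.135 to 33.1 ± 3.83 CPM (n = 4 each), or 32.9-fold, and Chst1 from 1.69 ± 0.0583 to 51.3 ± 6.25, or 30.2-fold. Lyz1 (chromosome 10, 117287797 to 117292868) fell from 172 ± 9.88 to 6.44 ± 0.296 (-4.74 ± 0.0619), and Lyz2 from 7207 ± 301 to 2582 ± 133, with reads that could be shared between these near-identical genes. The test called 2276 genes higher and 2650 lower, 188 and 465 of them at least 2-fold (105 higher under a filter of 1 CPM in 4 libraries). Higher genes made up 46.2% of the calls, and 53.5% under upper-quartile scaling. They also outnumbered the lower ones without ATP11A/C KD 2 (2594 and 2542).

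Other genes higher in ATP11A/C KD by the fixed rule were the RNA-binding proteins Igf2bp1 (log2 fold change 3.74 ± 0.168) and Igf2bp3 (2.83 ± 0.0822), Ranbp3l (3.49), Trp53i11 (3.02), the phosphate transporter Slc20a1 (2.13, from 128 ± 2.73 to 564 ± 17.1 CPM), Dmwd (1.46), Bmf (1.32) and the sorting receptor Sort1 (1.23). The lower ones were Sash3, an adaptor of lymphocyte signalling (-3.18), Ccl5 (-3.07), the hyaluronan receptor Layn (-2.96), Acod1 (-2.85), Ifit3 (-2.74), Plxdc1 (-2.70), Zbp1 (-2.67), Ifi211 (-2.66) and Cd200r4 (-2.62). Stc1 was at 1.15 ± 0.127 CPM against 0 counts in Parental, at least 49.9-fold higher.

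All 44 tested interferon-stimulated genes were lower in ATP11A/C KD too, also when adjusted over the list alone (median -1.27, camera adjusted p = 7.56e-46, and 0.0156 with an estimated correlation). Oasl2, Rsad2 and Ifit2 had log2 fold changes of -2.19, -2.59 and -2.29, and Irf7 from 632 ± 18.3 to 249 ± 14.4 CPM. Inflammatory genes were lower in 18 of 29 cases and higher in 4 (19 and 4 when adjusted over the list alone; median -0.35, camera adjusted p = 5.63e-08). Il1rn, the antagonist of interleukin 1, fell from 54.6 ± 1.31 to 13.9 ± 1.75 CPM, whereas Tnf, at 59.1 ± 6.31 against 65.7 ± 3.7, was not called (-0.15 ± 0.0715, adjusted p = 0.101). Of 21 antigen presentation genes 14 were lower and 4 higher, the same when adjusted over the list alone (median -0.64, camera adjusted p = 7.35e-06). Psmb9 and Tap1 had log2 fold changes of -0.92 and -0.81.

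Opsonic and pattern receptors were lower in 18 of 26 cases and higher in 2 in ATP11A/C KD (19 and 2 when adjusted over the list alone; median -0.52, camera adjusted p = 2.18e-09). Msr1 fell from 322 ± 8.08 to 126 ± 12.2 CPM and the complement receptor C3ar1 from 68.6 ± 1.47 to 33.0 ± 2.4. Phosphatidylserine receptor and efferocytosis genes had 12 of 24 lower and 3 higher (12 and 4 when adjusted over the list alone; median -0.11, camera adjusted p = 0.00326). Gas6 fell from 41.4 ± 2.48 to 11.6 ± 1.15 CPM (-1.82 ± 0.0738), and the TAM receptor Axl from 3.30 ± 0.324 to 0.560 ± 0.18 (-2.54 ± 0.21). Dock1, an activator of Rac, fell by 0.73 on the log2 scale. Cd36, at 81.0 ± 8.38 against 85.0 ± 1.52 CPM, was not called (adjusted p = 0.452). Mfge8, a secreted bridge to phosphatidylserine, rose from 57.5 ± 3.58 to 76.4 ± 6.11.

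Of 24 genes of phosphatidylserine synthesis and lipid transfer, 15 were lower and 1 was higher in ATP11A/C KD, the same when adjusted over the list alone (median -0.18, camera adjusted p = 1.25e-04). Besides Osbpl8, Esyt1, a tether between the endoplasmic reticulum and the plasma membrane, fell from 164 ± 5.81 to 107 ± 7.29 CPM. P4-ATPases had 5 of 10 lower and none higher, also when adjusted over the list alone (median -0.12, camera adjusted p = 0.0115; adjusted p = 0.086 with an estimated correlation). That list's call ended without ATP11A/C KD 1 (adjusted p = 0.052). Scramblases, with 8 of 13 lower and 2 higher, the same when adjusted over the list alone, were not called (camera adjusted p = 0.0505), but were under upper-quartile scaling (0.0451). Plscr4 and Plscr3 fell by 1.17 and 0.49 on the log2 scale.

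Neither LC3-associated phagocytosis (4 of 26 higher and 7 lower, the same when adjusted over the list alone; camera adjusted p = 0.375) nor canonical autophagy (3 of 29 higher and 10 lower, the same when adjusted over the list alone; 0.129) was called in ATP11A/C KD. Map1lc3b rose from 65.4 ± 1.39 to 83.8 ± 1.65 CPM (0.36 ± 0.0387), and Cybb fell by 0.34. Tecpr1, which has been linked to the fusion of autophagosomes with lysosomes, fell from 36.4 ± 3.06 to 22.1 ± 1.78. Lysosomal genes were lower in 36 of 47 cases and higher in 3 (36 and 4 when adjusted over the list alone; median -0.27, camera adjusted p = 5.48e-13). Gpnmb, a glycoprotein of lysosomes and endosomes, fell from 2363 ± 66.2 to 623 ± 28.6 CPM (-1.92 ± 0.0451), and Ctss and Ctsb by 1.00 and 0.78 on the log2 scale.

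The unfolded protein response list was higher in ATP11A/C KD: 18 of 30 genes were higher and 4 lower, the same when adjusted over the list alone (median 0.14, camera adjusted p = 6.31e-05). Creld2 rose from 127 ± 6.12 to 184 ± 4.6 CPM (0.53 ± 0.0429), Manf by 0.48 and Herpud1 by 0.47, while Atf3 fell from 70.9 ± 3.56 to 38.1 ± 2.09. Targets of p53 were higher, with 9 of 18 higher and 2 lower, the same when adjusted over the list alone (median 0.18, camera adjusted p = 0.00799). Phlda3 rose from 4.96 ± 0.801 to 10.6 ± 1.28 CPM (1.08 ± 0.122), Eda2r by 1.37, Sesn1 by 0.76 and Zmat3 by 0.53 on the log2 scale. Cholesterol synthesis genes were lower in 13 of 24 cases and higher in 2, the same when adjusted over the list alone (median -0.12, camera adjusted p = 0.00503; adjusted p = 0.053 with an estimated correlation), and Insig1 fell by 0.31.

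LXR targets had 10 of 17 lower and 2 higher in ATP11A/C KD, the same when adjusted over the list alone (camera adjusted p = 0.00187; adjusted p = 0.152 with an estimated correlation). Lpl and the cholesterol exporter Abca1 had log2 fold changes of -0.92 and -0.98. Glycolysis and hypoxia genes had 13 of 25 lower and none higher, also when adjusted over the list alone (camera adjusted p = 0.00157; adjusted p = 0.443 with an estimated correlation). Egln3, an oxygen-sensing hydroxylase, fell from 3.95 ± 0.263 to 0.887 ± 0.134 CPM. Osteoclast genes (12 of 18 lower and 3 higher, the same when adjusted over the list alone; median -0.46, camera adjusted p = 0.00187) and macrophage identity genes (15 of 22 lower and 3 higher, 17 and 3 when adjusted over the list alone; median -0.34, 1.03e-05) were lower. Siglec1 fell by 2.48, while Adgre1, which encodes the macrophage marker F4/80, rose from 67.3 ± 2.16 to 104 ± 5.22 CPM. Cell cycle genes were not called (8 of 35 higher and 6 lower, the same when adjusted over the list alone; camera adjusted p = 0.479).

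CDC50A KD was compared with Parental to see which genes differ when the shared flippase subunit is targeted. Hpgd rose from 1.00 ± 0.135 to 56.4 ± 3.48 CPM (n = 4 each), or 56.2-fold, and Chst1 from 1.69 ± 0.0583 to 89.7 ± 9.79, or 52.9-fold. Lyz1 fell from 172 ± 9.88 to 9.86 ± 0.513 CPM (-4.13 ± 0.0595), and Gas6 from 41.4 ± 2.48 to 6.93 ± 0.427 (-2.58 ± 0.0792). Interferon-stimulated genes, lysosomal genes and opsonic and pattern receptor genes were lower, and genes of the unfolded protein response were higher. In all, 3189 genes were higher and 3416 lower, 211 and 629 of them at least 2-fold (118 higher under a filter of 1 CPM in 4 libraries).

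The other genes higher in CDC50A KD by the fixed rule were Igf2bp1 (4.28 ± 0.166), Ranbp3l (3.75), Trp53i11 (3.74), Igf2bp3 (from 1.92 ± 0.112 to 15.4 ± 0.758 CPM), the endosomal exchanger Slc9a9 (2.15), Slc20a1 (1.98), the transcription factor Runx3 (1.91) and Dmwd (1.63). The lower ones were Slfn4 (-3.94 ± 0.335, with a wide spread in Parental at 313 ± 109 CPM), Cd200r4 (-3.30), Sash3 (-3.02) and Layn (-2.97). They also included the receptor gene Lilr4b (-2.96, whose reads could be shared with its paralog Lilrb4a), Opcml (-2.73), Plxdc1 (-2.62) and the spectrin gene Sptbn1 (-2.48).

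All 44 tested interferon-stimulated genes were lower in CDC50A KD as well, also when adjusted over the list alone (median -0.89, camera adjusted p = 2.79e-29, and 0.034 with an estimated correlation). Isg15 was at 56.5 ± 6.84 CPM against 118 ± 5.32, and Oasl2, Ifit2 and Stat2 fell by 1.38, 1.77 and 1.16 on the log2 scale. Inflammatory genes had 18 of 29 lower and 3 higher (18 and 4 when adjusted over the list alone; median -0.34, camera adjusted p = 1.31e-05). Acod1 fell from 48.3 ± 1.03 to 8.85 ± 1.44 CPM and Tnf from 65.7 ± 3.7 to 51.8 ± 3.69. Antigen presentation genes had 14 of 21 lower and 3 higher (16 and 3 when adjusted over the list alone; camera adjusted p = 0.00207; adjusted p = 0.138 with an estimated correlation). Nlrc5, the transactivator of class I genes, fell by 1.10.

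The unfolded protein response list was higher in CDC50A KD, with 22 of 30 genes higher and 3 lower, the same when adjusted over the list alone (median 0.35, camera adjusted p = 1.35e-08). Hspa5 rose from 2358 ± 47 to 3075 ± 53.4 CPM (0.38 ± 0.0392), Creld2 from 127 ± 6.12 to 236 ± 7.74 (0.89 ± 0.043), and the secreted factor Manf and the co-chaperone Dnajc3 by 0.75 and 0.74 on the log2 scale. Atf3 fell to 32.4 ± 1.25 CPM. Cell cycle genes were higher in 19 of 35 cases and lower in 4 (20 and 5 when adjusted over the list alone; median 0.14, camera adjusted p = 6.87e-04; adjusted p = 0.053 with an estimated correlation). The replication genes Mcm5 and Mcm3 rose by 0.30 and 0.29.

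Lysosomal genes had 33 of 47 lower and 3 higher in CDC50A KD (35 and 4 when adjusted over the list alone; median -0.25, camera adjusted p = 1.44e-09). Gpnmb fell to 557 ± 27.7 CPM (-2.08 ± 0.0453). Osteoclast genes had 12 of 18 lower and 5 higher, the same when adjusted over the list alone (median -0.60, camera adjusted p = 0.00503). The protease Ctsk fell from 2.78 ± 0.262 to 0.230 ± 0.0516 CPM (-3.60 ± 0.226), and Car2 rose from 376 ± 8.12 to 903 ± 19.4. Opsonic and pattern receptors had 17 of 26 lower and 2 higher, the same when adjusted over the list alone (median -0.49, camera adjusted p = 1.36e-06). The integrin gene Itgax fell from 3.31 ± 0.0884 to 0.752 ± 0.096 CPM. Phosphatidylserine receptor and efferocytosis genes had 12 of 24 lower and 4 higher, the same when adjusted over the list alone (camera adjusted p = 0.00659; adjusted p = 0.0512 with an estimated correlation). Mfge8 rose from 57.5 ± 3.58 to 90.0 ± 5.29.

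In the LC3-associated phagocytosis list of CDC50A KD, 7 of 26 genes were higher and 8 lower, the same when adjusted over the list alone, and the list was not called (median -0.04, mean 0.02 and direction of the test higher, camera adjusted p = 0.833). Map1lc3b rose from 65.4 ± 1.39 to 108 ± 1.97 CPM (0.73 ± 0.0387), the GTPase Rac2 rose by 0.42, and Atg16l1, which attaches LC3 to membranes, fell from 35.5 ± 3.42 to 23.2 ± 0.792 (-0.61 ± 0.0911). Canonical autophagy was not called (2 of 29 higher and 11 lower, 1 and 10 when adjusted over the list alone; camera adjusted p = 0.148), and Tecpr1 went from 36.4 ± 3.06 to 18.1 ± 0.833 CPM. Phosphatidylserine synthesis and transfer genes were lower in 15 of 24 cases and higher in 2 (16 and 2 when adjusted over the list alone; median -0.16, camera adjusted p = 0.00192). Osbpl10 fell from 3.06 ± 0.302 to 0.634 ± 0.265 CPM.

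Scramblases had 9 of 13 lower and 2 higher in CDC50A KD, the same when adjusted over the list alone (camera adjusted p = 0.0283; adjusted p = 0.0571 with an estimated correlation). Xk fell from 0.810 ± 0.155 to 0.117 ± 0.0886 CPM, and Tmem41b rose by 0.34. That call ended without CDC50A KD 1 (adjusted p = 0.0511) and under a filter of 1 CPM in 4 libraries (0.0811). P4-ATPases had 5 of 10 lower and none higher, also when adjusted over the list alone (camera adjusted p = 0.0237; adjusted p = 0.125 with an estimated correlation), and the call ended without Parental 1, 2 or 4 or CDC50A KD 1 or 3 (adjusted p = 0.0583, 0.0603, 0.0614, 0.0503 and 0.0695). Cholesterol synthesis genes had 16 of 24 lower and 2 higher, the same when adjusted over the list alone (camera adjusted p = 0.00595; adjusted p = 0.055 with an estimated correlation), and Hmgcs1 fell by 0.49. LXR targets had 8 of 17 lower and 2 higher, the same when adjusted over the list alone (camera adjusted p = 0.0192; adjusted p = 0.296 with an estimated correlation).

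Macrophage identity genes (12 of 22 lower and 5 higher, 12 and 6 when adjusted over the list alone; camera adjusted p = 0.0622), glycolysis and hypoxia genes (10 of 25 lower and 5 higher, the same when adjusted over the list alone; 0.406) and p53 targets (9 of 18 lower and 4 higher, 10 and 4 when adjusted over the list alone; 0.301) were not called in CDC50A KD. The identity list passed the threshold without Parental 3 or 4 or CDC50A KD 1 (adjusted p = 0.0482, 0.035 and 0.0455) and with no low-count filter (0.0201). Within it Lyz2 fell from 7207 ± 301 to 2859 ± 60.1 CPM, Mpeg1, perforin-2, fell by 1.04, and Maf fell from 2.37 ± 0.826 to 0.0270 ± 0.0365 CPM.

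**Figure D2:**
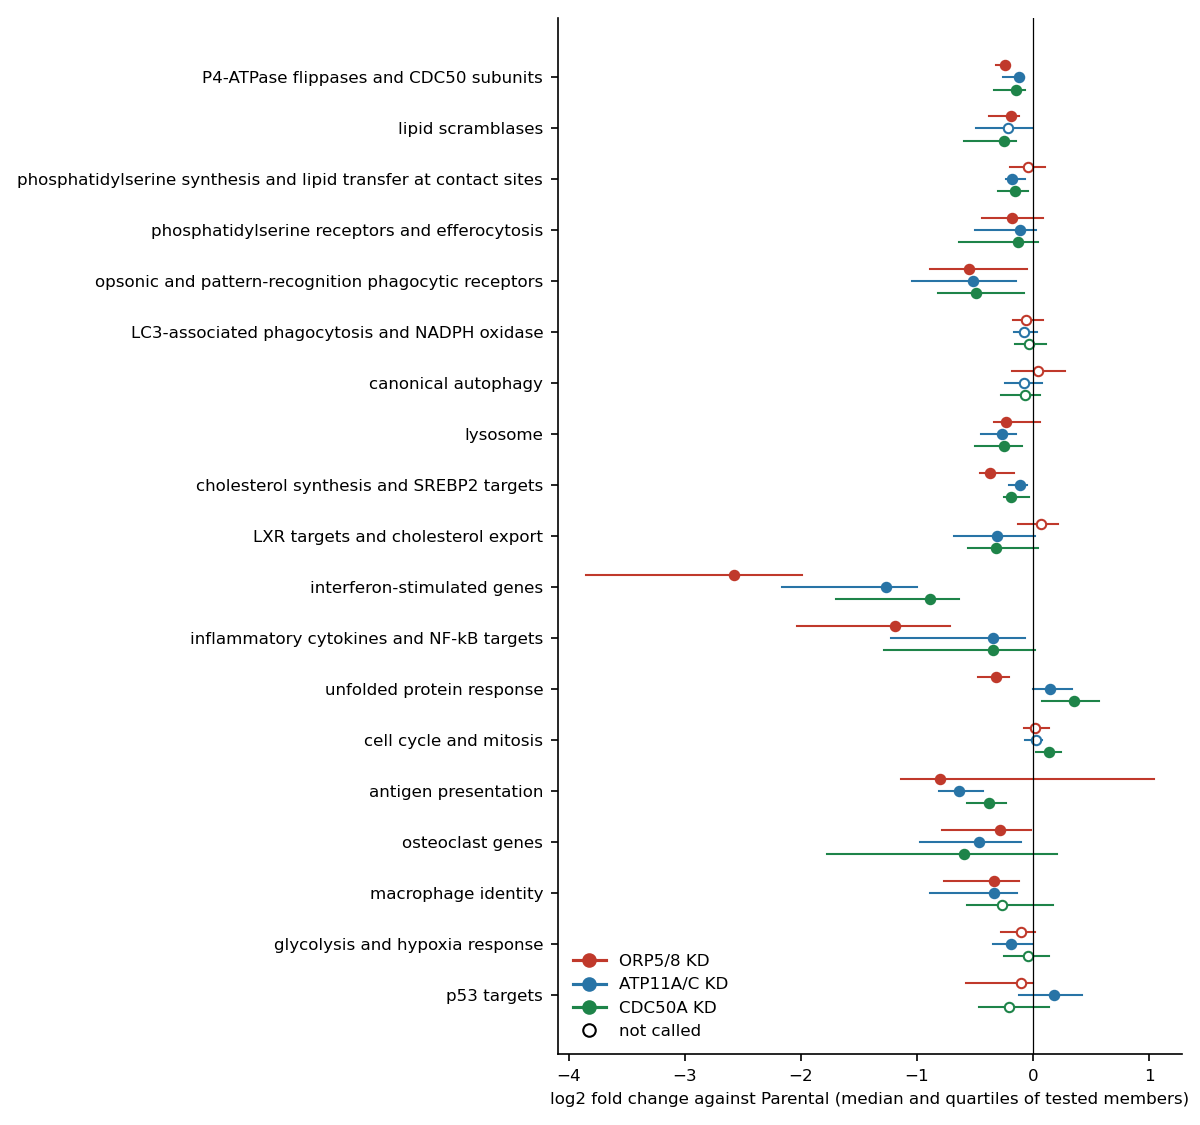
Median log2 fold change against Parental (horizontal axis) of the tested members of 19 gene lists in each of the 3 KD groups (points), with the 25th and 75th percentiles of the members (lines); filled points mark lists called by camera at an adjusted p under 0.05. Interferon-stimulated genes have medians of -2.58, -1.27 and -0.89 in ORP5/8, ATP11A/C and CDC50A KD, and the unfolded protein response is at -0.32, 0.14 and 0.35.

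CDC50A KD was compared with ATP11A/C KD to see where the shared subunit and these flippases differ. Atp11a was 2.01-fold higher in CDC50A KD, at 43.1 ± 1.36 against 21.4 ± 0.843 CPM (n = 4 each). The p53 target Phlda3 was lower in CDC50A KD, at 3.63 ± 0.543 against 10.6 ± 1.28 CPM (-1.55 ± 0.126), as was Ppic (-1.10). Targets of p53 were lower in 12 of 18 cases and higher in none (15 lower when adjusted over the list alone; median -0.32, camera adjusted p = 9.32e-10), including Eda2r (-1.22 ± 0.189) and Zmat3 (-0.75 ± 0.0766). Genes of the unfolded protein response were higher in 19 of 30 cases and lower in 3 (21 and 3 when adjusted over the list alone; median 0.20, camera adjusted p = 3.8e-08), and cell cycle genes in 15 of 35 with none lower (16 when adjusted over the list alone; median 0.10, 6.91e-06). Interferon-stimulated genes were higher in 34 of 44 cases and lower in 1 (35 and 1 when adjusted over the list alone; median 0.42, camera adjusted p = 4.93e-20; adjusted p = 0.117 with an estimated correlation). Rsad2 stood at 30.7 ± 5.01 against 16.5 ± 0.907 CPM.

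Antigen presentation (11 of 21 higher), macrophage identity (12 of 22) and glycolysis and hypoxia genes (8 of 25) were also called higher in CDC50A KD than in ATP11A/C KD, with camera adjusted p = 0.00418, 3.24e-04 and 0.00286. None of these 3 calls held with an estimated correlation (adjusted p = 0.271, 0.0928 and 0.585), and that of glycolysis and hypoxia also ended without CDC50A KD 4 (0.0721). The counts when adjusted over the list alone were 11, 12 and 14 higher. Across genes 1763 were higher and 1665 lower, 30 and 189 at least 2-fold (8 and 102 under a filter of 1 CPM in 4 libraries, and 54 higher with no filter). Higher genes made up 51.4% of the calls, 49.2% with DESeq2 size factors and 43.0% under upper-quartile scaling. Lower genes also outnumbered higher ones without each of the 8 libraries in turn, under the 1 CPM filter (1756 and 1614), in a fit of these groups alone (1367 and 1206) and by the DESeq2 test (1868 and 1833). The count of higher genes dropped to 1118 without ATP11A/C KD 3 and to 1169 without CDC50A KD 3. Cd24a, Isg20 and Slpi were higher in CDC50A KD by 0.95, 0.93 and 0.91 on the log2 scale, and Pde1b, Ankrd16 and Rsrp1 had log2 fold changes of -1.26, -1.24 and -1.18.

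ORP5/8 KD differed from ATP11A/C KD in the opposite direction of the unfolded protein response: 25 of 30 genes were lower and 1 higher in ORP5/8 KD (26 and 1 when adjusted over the list alone; median -0.50, camera adjusted p = 8.49e-16). Creld2 was 94.1 ± 3.96 CPM in ORP5/8 KD and 184 ± 4.6 in ATP11A/C KD, and Edem1 282 ± 10.4 and 573 ± 16.1. Egln3 (3.78 ± 0.169), Cxcr4 (3.27), Ndst1 (3.02), Sash3 (2.85) and the T cell costimulatory receptor gene Cd28 (2.66) were higher in ORP5/8 KD. Apol9b (-4.30), Apol9a (-3.94), Dmwd (-2.98), Igf2bp1 (-2.63) and Oasl2 (-2.56) were lower. Interferon-stimulated genes were lower in 43 of 44 cases and higher in none, also when adjusted over the list alone (median -1.33, camera adjusted p = 7.74e-37, and 0.0343 with an estimated correlation). Inflammatory genes were lower in 23 of 29 with 4 higher, the same when adjusted over the list alone (median -0.71, camera adjusted p = 1.43e-10). H2-Ab1 was 2.73 ± 0.265 CPM against 0.232 ± 0.0707 (3.51 ± 0.23), and Gas6 70.5 ± 5.83 against 11.6 ± 1.15 (2.59 ± 0.0735).

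Cholesterol synthesis genes were lower in ORP5/8 KD than in ATP11A/C KD (15 of 24 and none higher, 17 lower when adjusted over the list alone; camera adjusted p = 9.99e-06), as were p53 targets (14 of 18 and 2 higher, the same when adjusted over the list alone; 6.77e-05) and dendritic cell markers (3 of 5 and none higher, also when adjusted over the list alone; 0.027). Lysosomal genes (24 of 47 higher and 5 lower, the same when adjusted over the list alone; 1.3e-05), canonical autophagy (14 of 29 and 6 lower, 15 and 6; 0.0132), LXR targets (8 of 17 and 2 lower, the same; 0.0132) and phosphatidylserine synthesis and transfer (12 of 24 and 3 lower, the same; 0.0287) were higher. The calls of the dendritic, lysosomal, autophagy, LXR and phosphatidylserine lists were lost, with adjusted p = 0.0928, 0.174, 0.156, 0.373 and 0.115 with an estimated correlation. The LXR call also ended without ATP11A/C KD 2 (0.0551). In total 2392 genes were higher and 2678 lower, 311 and 288 at least 2-fold (209 and 211 under a filter of 1 CPM in 4 libraries, 298 and 300 without ORP5/8 KD 4). Higher genes made up 47.2% of the calls, and 60.5% under upper-quartile scaling.

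The most genes differed between ORP5/8 KD and CDC50A KD: 3603 were higher and 3848 lower in ORP5/8 KD, 694 and 372 at least 2-fold (446 higher under a filter of 1 CPM in 4 libraries). Cxcr4 was 17.2-fold higher in ORP5/8 KD, at 17.9 ± 1.1 against 1.01 ± 0.366 CPM (n = 4 each), Gas6 10.2-fold, at 70.5 ± 5.83 against 6.93 ± 0.427, and H2-Ab1 at 2.73 ± 0.265 against 0.211 ± 0.0432 (3.68 ± 0.239). Rgs11 and Opcml had log2 fold changes of 3.17 and 2.98, and Ndst1 stood at 36.7 ± 1.26 against 4.60 ± 0.433 CPM. Apol9b, Apol9a, Oasl2, Isg15 and Isg20 were lower in ORP5/8 KD, at -5.12, -4.65, -3.37, -3.24 and -3.19. Genes of the unfolded protein response were lower in 26 of 30 cases and higher in 1, the same when adjusted over the list alone (median -0.69, camera adjusted p = 2.72e-14). Hspa5 stood at 1777 ± 91.3 against 3075 ± 53.4 CPM. Higher genes made up 48.4% of the calls, and 60.7% under upper-quartile scaling. They also outnumbered the lower ones without each CDC50A KD library in turn, under the 1 CPM filter (3604 and 3462) and in a fit of these groups alone (3749 and 3712).

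Interferon-stimulated genes were lower in all 44 cases in ORP5/8 KD than in CDC50A KD, also when adjusted over the list alone (median -1.65, camera adjusted p = 1.44e-31; adjusted p = 0.0511 with an estimated correlation). Inflammatory genes were lower in 21 of 29 with 2 higher, the same when adjusted over the list alone (median -0.73, camera adjusted p = 3.78e-08), and cholesterol synthesis genes in 14 of 24 with 1 higher (15 and 2 when adjusted over the list alone; 0.00308; adjusted p = 0.0795 with an estimated correlation). Lysosomal genes were higher in 23 of 47 and lower in 10 (24 and 10 when adjusted over the list alone; camera adjusted p = 0.00418; adjusted p = 0.373 with an estimated correlation).

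**Figure D3:**
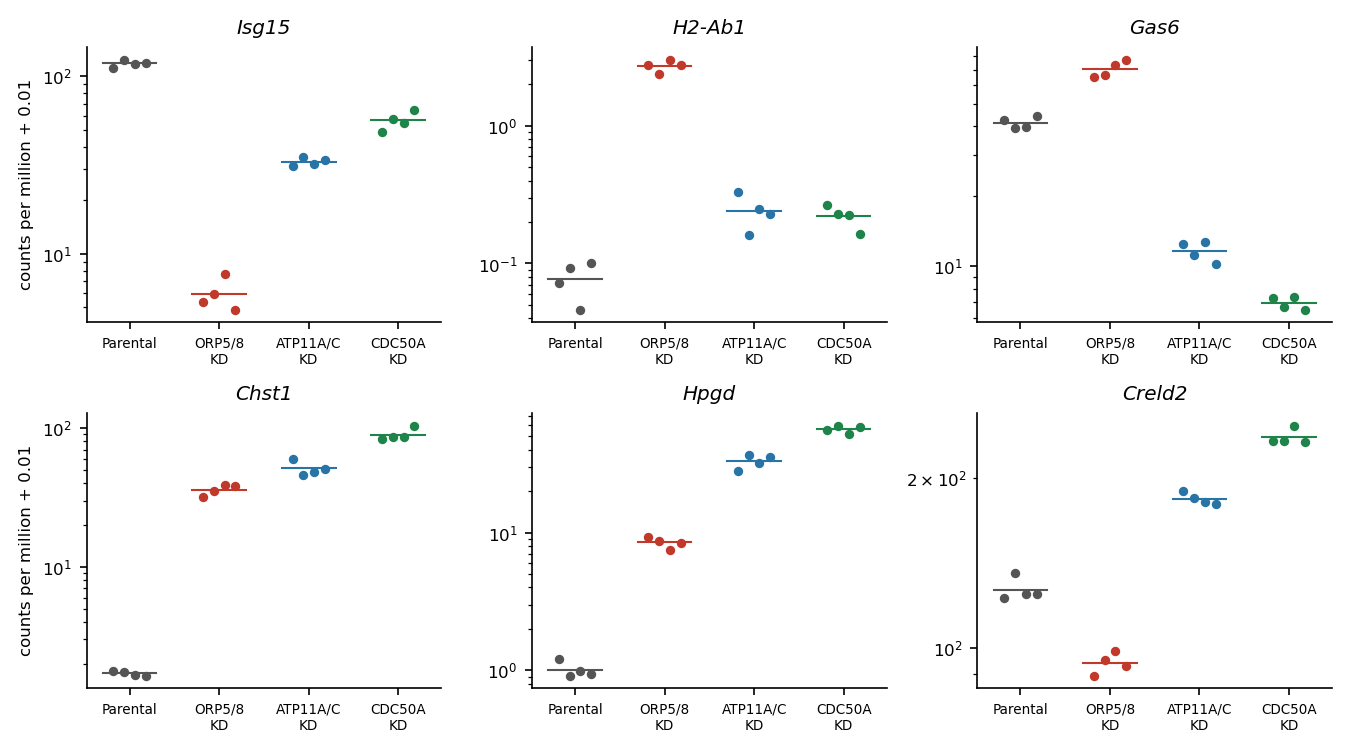
Level in counts-per-million on a log axis (0.01 added to each value) of Isg15, H2-Ab1, Gas6, Chst1, Hpgd and Creld2 in each of the 16 libraries (points) by group, with a horizontal line at the group mean. Isg15 is lowest in ORP5/8 KD at 5.97 CPM and H2-Ab1 highest there at 2.73, while Gas6 falls from 41.4 in Parental to 11.6 and 6.93 in ATP11A/C and CDC50A KD and rises to 70.5 in ORP5/8 KD.

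Changes shared by the KD groups were counted among the 13107 tested genes. In all 3 groups 845 genes were higher and 1434 lower, and under upper-quartile scaling 1295 and 1245. Independent lists of the same sizes would share 122 and 168. In 20 simulations of unchanged groups against the same Parental libraries 0 genes were shared, which sets no reference for these counts, since a simulated comparison with no change called 0 genes. By the fixed rule the shared higher genes were Chst1, Ranbp3l, Trp53i11, Sort1 and Sla, an adaptor that dampens receptor signalling. Sla stood at 21.7 ± 1.19 CPM in Parental and 70.6 ± 1.84, 43.2 ± 3.08 and 44.3 ± 4.66 in ORP5/8, ATP11A/C and CDC50A KD. The shared lower genes were Layn, Lyz1, Acod1, Ccl5 and Slfn4. The cathepsin gene Ctsh rose in each, from 0.109 ± 0.0412 CPM to 0.614 ± 0.0739, 0.558 ± 0.114 and 1.08 ± 0.217.

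ATP11A/C KD and CDC50A KD shared 1683 higher and 2091 lower genes, with 56 called in opposite directions (554 and 691 for independent lists). ORP5/8 KD and ATP11A/C KD shared 1185 and 1767, with 346 opposite (500 and 643). ORP5/8 KD and CDC50A KD shared 1133 and 1628 (700 and 829), with 845 opposite, among them Hspa5, Mfge8 and Gas6. The values in brackets are for shared higher and lower genes. No value for independent lists was computed for opposite calls, so these counts have no reference. Under upper-quartile scaling the shared higher and lower genes of these pairs, in this order, were 2008 and 1958, 1828 and 1477, and 1707 and 1409. With Parental 1 and 2 used for one group and 3 and 4 for the other, and the reverse, the shared higher genes were 904 and 1206 for ATP11A/C with CDC50A KD, 671 and 647 for ORP5/8 with ATP11A/C KD, and 664 and 784 for ORP5/8 with CDC50A KD. The shared lower genes under these splits were 1588 and 1740, 1408 and 1401, and 1306 and 1327.

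Across genes, which are not independent replicates, the log2 fold changes of ATP11A/C KD and CDC50A KD had a covariance of 0.269 (Pearson r = 0.805), against a simulated 0.0203 (r = 0.510) for unchanged groups that share the Parental libraries. For ORP5/8 KD the covariance was 0.222 with ATP11A/C KD (r = 0.638; simulated 0.0202, r = 0.514) and 0.185 with CDC50A KD (r = 0.459; simulated 0.0201, r = 0.504). The log2 fold changes of all 13107 tested genes, called or not, had the same sign in 77.6%, 70.4% and 61.3% of cases for these pairs in this order, against 66.8%, 66.8% and 66.9% in the simulations. The simulated r and shares come from noise in the shared Parental libraries alone. They set no reference for groups with many called genes. With split controls, r was 0.626 and 0.714, 0.503 and 0.544, and 0.326 and 0.425 for these pairs. The sign was then the same in 70.1% and 77.4%, 64.8% and 69.0%, and 56.5% and 62.4% of cases. The mitochondrial share of counts given above was also higher in all 3 KD groups than in Parental.

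Markers of other cell types were mostly below the filter. No epithelial marker was tested. Of 13 fibroblast markers, Pdgfrb and Acta2 were tested and neither was called in any KD group against Parental (camera adjusted p = 0.837, 0.543 and 0.864 in ORP5/8, ATP11A/C and CDC50A KD). The dendritic cell list, with 5 of 12 markers tested, was not called against Parental (camera adjusted p = 0.406, 0.498 and 0.991), and in CDC50A KD its median of -0.18 and mean of 0.48 differed in sign. Bst2, which is also on the interferon list, fell from 348 ± 24.2 CPM to 92.6 ± 7.64, 220 ± 14.6 and 264 ± 20.6, and Siglech rose from 0.106 ± 0.0952 to 0.518 ± 0.283, 0.704 ± 0.282 and 0.621 ± 0.206. The lymphocyte marker tested was Lck, which fell from 4.48 ± 0.277 CPM to 2.11 ± 0.189, 2.90 ± 0.436 and 3.37 ± 0.221. The neutrophil marker tested was Csf3r, the receptor of granulocyte colony-stimulating factor, which rose from 6.80 ± 0.251 to 22.6 ± 0.636, 12.8 ± 1.22 and 9.32 ± 0.877.

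With an estimated correlation in place of the preset one, 7 of the 12 lists called in ORP5/8 KD against Parental held, 11 of 15 in ATP11A/C KD and 7 of 14 in CDC50A KD. In the direct comparisons 3 of 7 held for CDC50A KD against ATP11A/C KD, 5 of 10 for ORP5/8 KD against ATP11A/C KD and 2 of 5 for ORP5/8 KD against CDC50A KD. For the last comparison 8 lists were called with no low-count filter and 9 under upper-quartile scaling. In ORP5/8 KD the lists that held were P4-ATPases, opsonic receptors, cholesterol synthesis, interferon-stimulated genes, inflammatory genes, the unfolded protein response and macrophage identity.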

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

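The patterns weighed in this part were chosen after the main results were seen. The tests of the neighbours of Osbpl8 and of a non-targeting construct were also chosen after results bearing on them were seen, while the predictions of the other tests were written before these were run. The numbers of genes called were larger for the labelled groups than for any other of the 35 splits of the 8 libraries. They were 6059, 4926 and 6605 genes in ORP5/8, ATP11A/C and CDC50A KD against Parental, with 0 as the highest other value each time. At least 2-fold changes numbered 857, 653 and 840, again with 0 as the highest other value. Between KD groups the calls were 3428 for CDC50A KD against ATP11A/C KD (highest other 617; 219 and 30 at least 2-fold), 5070 for ORP5/8 KD against ATP11A/C KD (505; 599 and 6) and 7451 for ORP5/8 KD against CDC50A KD (1; 1066 and 1). In each of these counts 1 of 35 splits, the labelled one, was as large, which is the smallest share possible. Every other split puts libraries of both groups on each side, which widens the spread within a side, so few calls are likely there. The splits with 617 and 505 calls both moved ATP11A/C KD 1, exchanged with CDC50A KD 4 and with ORP5/8 KD 1. The count of splits shows that libraries resemble others of their group. It cannot exclude a chance difference between cultures, since the replicates may be technical, nor tell such a difference from an effect of the knockdown. For the numbers of lists called, adjusted within each comparison, chance cannot be excluded by this count: 5 of 35 splits gave as many as the 12 lists of ORP5/8 KD (highest other 12), 2 of 35 as many as the 16 of ATP11A/C KD (16) and 5 of 35 as many as the 14 of CDC50A KD (15). The other splits with as many lists kept 3 libraries of each group together and so hold part of the labelled difference. The 18 splits with 2 libraries of each group called at most 2, 3 and 3 lists, but set against these alone, a choice made after they were seen, the labelled one would be 1 of 19, a share of 0.0526.

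Interferon-stimulated genes were lower in all 3 KD groups than in Parental. The scaling between libraries is unlikely to account for this, since under both other scalings the highest median log2 fold change was -0.88. A single Parental library with raised levels is ruled out by a highest median of -0.86 with each Parental library left out in turn. A state of the Parental libraries, or a difference between Parental and all cells with an sh construct, would be common to the KD groups. In ORP5/8 KD the median was -1.33 against ATP11A/C KD, with 43 of 44 genes lower and none higher. Against CDC50A KD it was -1.65, with all 44 lower. With an estimated correlation the camera adjusted p was 0.0343 and 0.0511. These differences argue against either as the only cause in ORP5/8 KD. Whether either, or the knockdowns, lies behind the part shared by all KD groups remains open, because 0 libraries with a non-targeting construct were analysed.

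Osbpl8 was lower in all 3 KD groups than in Parental, not only where it was targeted. A local difference in copy number that spans its neighbours would likely lower them. However, the lowest median log2 fold change of the 14 other tested genes within 4 Mb was -0.076. Single neighbours ran from -1.5 in CDC50A KD to 0.792 in ORP5/8 KD. The median cannot detect a loss confined to Osbpl8 or a few of these genes. ORP5/8 KD cells in place of, or mixed into, the other libraries would carry the genes raised in ORP5/8 KD along: over 305 such genes the median share of the excess was 0.369 in ATP11A/C KD (95% bootstrap interval 0.292 to 0.425, with 0.884 needed for Osbpl8) and 0.191 in CDC50A KD (0.125 to 0.271, with 0.928 needed). Neither interval reaches the share needed. A difference between Parental and all cells with an sh construct may account for it and remains open, with 0 libraries carrying a non-targeting construct.

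The unfolded protein response was lower in ORP5/8 KD and higher in the other KD groups than in Parental, and was picked out as a difference in direction between groups. Its median log2 fold change was -0.50 in ORP5/8 KD against ATP11A/C KD (camera adjusted p = 8.49e-16) and -0.69 against CDC50A KD (2.72e-14).

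A library was also picked out where it lay far from the other 3 of its group, with a gap to the nearest value larger, as a share of the range of the 4, than the 0.05 critical value of Dixon's test. Chance alone picks out about 1 in 20 groups. Here 42 of 688 groups of 4 values were picked out, where 34.4 are expected by chance, over 172 measures: library totals, target genes, gene lists and the genes named in the text. CDC50A KD 4 was picked out 8 times and no other library more than 5 times. In the following, each value is given with the lowest and highest of the other 3 libraries and the ratio of gap to range.

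The library Parental 1 stood apart from the other 3 of its group in the mean log2 CPM of opsonic and pattern-recognition phagocytic receptors (5.48 against 5.51, ratio 0.958). In Parental 2 the values apart from those of its group were Hspa5 (2429 CPM against 2335, ratio 0.996) and Creld2 (136 CPM against 122 to 125, ratio 0.843). Apart from its group, Parental 3 had Osbpl8 (346 CPM against 333 to 335, ratio 0.872), the mean log2 CPM of dendritic cell markers (0.42 against 0.96 to 1.05, ratio 0.857) and H2-Eb1 (0.1803 CPM against 0 to 0.0308, ratio 0.8293). For Parental 3 such values were found in Cd36 (87.2 CPM against 84.0 to 84.4, ratio 0.869) and Plxdc1 (13.6 CPM against 15.3 to 15.5, ratio 0.931). The library Parental 4 stood apart from the other 3 of its group in B2m (819.9 CPM against 870.0 to 875, ratio 0.914) and Csf3r (7.17 CPM against 6.62 to 6.71, ratio 0.836).

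In ORP5/8 KD 1 the values apart from those of its group were the mean log2 CPM of P4-ATPase flippases and CDC50 subunits (5.28 against 5.19 to 5.20, ratio 0.890), Msr1 (143 CPM against 126 to 128, ratio 0.873) and Ifit2 (11.2 CPM against 10.0 to 10.2, ratio 0.859). Apart from its group, ORP5/8 KD 1 had Plscr3 (19.1 CPM against 22.1 to 22.7, ratio 0.833) and Xk (0.394 CPM against 0.320 to 0.327, ratio 0.903). For ORP5/8 KD 2 such values were found in Zmat3 (67.1 CPM against 62.7 to 63.0, ratio 0.917). The library ORP5/8 KD 3 stood apart from the other 3 of its group in the mean log2 CPM of interferon-stimulated genes (3.53 against 3.43 to 3.45, ratio 0.849), Irf7 (49.7 CPM against 41.7 to 42.2, ratio 0.936) and Sla (67.9 CPM against 71.3 to 71.9, ratio 0.862). In ORP5/8 KD 4 the values apart from those of its group were Lyz2 (3916 CPM against 4229.6 to 4291, ratio 0.837) and Igf2bp1 (2.04 CPM against 1.55 to 1.57, ratio 0.955).

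Apart from its group, ATP11A/C KD 1 had Tnf (49.6 CPM against 61.8 to 62.7, ratio 0.928), Marcksl1 (100.5 CPM against 88.7 to 90.4, ratio 0.857) and Psmb8 (103 CPM against 95.03 to 96.3, ratio 0.846). For ATP11A/C KD 1 such values were found in Gpnmb (666 CPM against 605 to 612, ratio 0.882) and Opcml (7.30 CPM against 5.99 to 6.10, ratio 0.914). The library ATP11A/C KD 2 stood apart from the other 3 of its group in Lpl (638 CPM against 666 to 670.1, ratio 0.876). In ATP11A/C KD 3 the values apart from those of its group were the mean log2 CPM of p53 targets (5.04 against 4.98 to 4.99, ratio 0.848). Apart from its group, ATP11A/C KD 4 had Fdft1 (67.1 CPM against 70.6 to 71.1, ratio 0.857).

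For CDC50A KD 1 such values were found in H2-Eb1 (0.0515 CPM against 0, ratio 1.00), Herpud1 (148 CPM against 152 to 153, ratio 0.893) and Runx3 (14.4 CPM against 13.7 to 13.8, ratio 0.840). The library CDC50A KD 2 stood apart from the other 3 of its group in Tmem41b (112 CPM against 102 to 103, ratio 0.858). In CDC50A KD 3 the values apart from those of its group were Creld2 (247 CPM against 232, ratio 0.959). Apart from its group, CDC50A KD 4 had Chst1 (104 CPM against 82.8 to 86.1, ratio 0.845), Ptgs2 (9.58 CPM against 10.9 to 11.1, ratio 0.886) and Ddit3 (12.9 CPM against 9.83 to 10.3, ratio 0.849). For CDC50A KD 4 such values were found in Il1rn (14.8 CPM against 17.995 to 18.4, ratio 0.878), Atf3 (34.2 CPM against 31.7 to 31.8, ratio 0.937) and Zmat3 (42.04 CPM against 49.5 to 50.2, ratio 0.912). The library CDC50A KD 4 stood apart from the other 3 of its group in Ctsk (0.153 CPM against 0.245 to 0.263, ratio 0.840) and Bst2 (295 CPM against 253 to 254, ratio 0.982).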

How the results depend on the processing

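Direction was followed for 552 values of single genes and 126 list results, not for the other called genes. Among these gene values, none called in the main fit changed direction under any alternative. No list called both in the main fit and under an alternative changed direction. The balance of higher and lower genes did change. Under upper-quartile scaling the share of higher genes among the calls went from 47.5% to 63.3% in ORP5/8 KD and from 46.2% to 53.5% in ATP11A/C KD against Parental. It went from 51.4% to 43.0% in CDC50A KD against ATP11A/C KD (49.2% with DESeq2 size factors), and in ORP5/8 KD from 47.2% to 60.5% against ATP11A/C KD and from 48.4% to 60.7% against CDC50A KD. With single libraries left out, the balance of the called genes turned in 2 of 8 fits for ORP5/8 KD and 1 for ATP11A/C KD against Parental, in 8 for CDC50A KD against ATP11A/C KD and in 4 for ORP5/8 KD against CDC50A KD. Of 38 counts of genes, overlaps and lists, 16 moved by more than 1.5 times under some alternative, none of them under DESeq2 size factors or the DESeq2 test. Of 552 values of single genes, 32 crossed the threshold under some alternative, and of 126 list results 38 did. Leaving out the genes of chromosome 12, chosen after seeing the data, left 293 genes at least 2-fold higher and 541 lower in ORP5/8 KD against Parental. Low counts limit what can be called, and Osbpl5 is below the filter.

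With a filter of 1 CPM in 4 libraries, which tests fewer genes, at least 2-fold higher genes numbered 185 in ORP5/8 KD, 105 in ATP11A/C KD and 118 in CDC50A KD against Parental, and 446 in ORP5/8 KD against CDC50A KD. For CDC50A KD against ATP11A/C KD there were 8 higher and 102 lower. With no filter that comparison had 54 genes at least 2-fold higher, and ORP5/8 KD against CDC50A KD had 8 lists called. Under upper-quartile scaling the shared higher genes were 1828 for ORP5/8 with ATP11A/C KD, 1707 for ORP5/8 with CDC50A KD and 1295 for all 3, and 9 lists were called in ORP5/8 KD against CDC50A KD. This scaling moved the median log2 fold change against Parental up by 0.0739 in ORP5/8 KD, 0.0244 in ATP11A/C KD and 0.0057 in CDC50A KD. An upward shift favours higher calls, but its part in these counts was not tested, nor was any other cause. With split controls, which leave 2 Parental libraries per KD group, the shared higher genes were 671 and 647 for ORP5/8 with ATP11A/C KD, 664 for ORP5/8 with CDC50A KD and 904 for ATP11A/C with CDC50A KD.

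With an estimated correlation 7 lists were called in ORP5/8 KD and 7 in CDC50A KD against Parental, 3 in CDC50A KD against ATP11A/C KD, 5 in ORP5/8 KD against ATP11A/C KD and 2 in ORP5/8 KD against CDC50A KD. Leaving out each library in turn, the genes higher in CDC50A KD than in ATP11A/C KD ran from 1118 to 1873 and Tmem30a in ATP11A/C KD from -0.23 to -0.14. The cause was not tested. With the replicate number as a block, 2823 genes were higher and 3138 lower in ORP5/8 KD, 2211 and 2599 in ATP11A/C KD, and 3122 and 3362 in CDC50A KD. The labels give no pairing. Of 24 pairs of libraries with the same number, 2 had a residual correlation above 0.1 (mean 0.007, against -0.002 for other pairs). By mean residual correlation, 8 of 16 libraries were closest to those of their own number, among 4 numbers. That count was not set against chance, so an effect of the replicate number is not excluded. The block ended the calls of H2-Eb1 and Ctsk in 1 comparison each, added that of Clec7a and that of the scramblase list in ATP11A/C KD, and changed no other call of the genes and lists named.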

Other observations

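The tests of chromosome 12 in this part were planned after a first look at all chromosomes, with their predictions written before they were run. In ORP5/8 KD the genes of chromosome 12 were higher as a block. The 484 tested genes of this chromosome had a median log2 fold change of 0.19 against Parental, while the medians of the 18 other autosomes ran from -0.04 to 0.06. Relative to the rest of the genome, the median over Parental was 0.18 ± 0.022 (SD, n = 4) in ORP5/8 KD, from 0.15 to 0.21 per library. It was -0.03 ± 0.028 in ATP11A/C KD and -0.03 ± 0.024 in CDC50A KD.

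A gain of chromosome 12 in these cells, or in a share of them, is a hypothesis that would raise the whole chromosome, and the lowest median over its 20 Mb bins was 0.126, above 0 throughout. A few strongly changed genes could not account for it, since 73.6% of the tested genes had a positive log2 fold change, against 42.8% to 59.5% on the other autosomes. This share goes with the raised median of the same genes and is not separate support. RNA alone cannot show a copy number, and no DNA data were analysed here.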
